A study of Mus musculus with 24 samples.

How the data were processed

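RNA was sequenced from mouse bone marrow-derived dendritic cells (BMDC) grown for 7 days in medium with GM-CSF. The cells came from wild-type (WT) mice or from mice that the labels call LCH or mutant, which carry the BRAF-V600E change of Langerhans cell histiocytosis. Cells were given a BRAF-V600E inhibitor for 1 h beforehand or no inhibitor, and all received LPS, at 100 ug per mL per the labels, a unit that could not be checked here, for 3 h and cycloheximide at 100 ug per mL before lysis. From each lysate an aliquot gave total RNA, and 500 uL of pooled gradient fractions holding mRNA with more than 2 polysomes gave polysome RNA. Genotype, inhibitor and RNA fraction make 8 groups of 3 libraries, 24 in all.

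The deposited raw table holds counts for 54309 gene models, made with Salmon and DESeq2 per the labels, which give no versions. These raw counts were used for every main result. The authors also deposited normalized counts, an expression signal scaled with DESeq2. The ratio of raw to normalized values differed between genes of a library by up to 20.4 times the ratio itself, so the signal was not used for tests. Per the file headers, 2 further deposited tables hold regularised log2 values (rlog), separately for total RNA and for polysome RNA, and these served as an alternative input. The labels name the build mm9, while the files name none. Only 4.24% of 21113 protein-coding symbols lay within 5000 bases of their GRCm38.p6 start. The file places Tnf (ENSMUSG00000024401.15) on the minus strand of chromosome 17 from 35418357 to 35420983. It places Braf (ENSMUSG00000002413.16) on the minus strand of chromosome 6 from 39580171 to 39702397. The 2684 gene models with no symbol of their own were kept under their identifiers.

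Columns carry pool letters (A, BD and C for WT, E, F and G or GH for LCH) and not the replicate numbers of the labels. Each column was assigned to its group by the genotype, inhibitor and fraction in its name. Pool GH in polysome RNA and pool G in total RNA were treated as the same pool. Libraries of WT and LCH share no pool, so the genotype comparisons had no pairing. Each value rests on 3 pools a group, and every p-value of a single gene measures the spread between these samples. P-values of gene lists set a list against other genes, so they also rest on the spread between genes. They treat genes as nearly independent unless the correlation was estimated.

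Counts were tested with edgeR 4.0.16 in R 4.3.3, using quasi-likelihood fits with robust dispersions, TMM scaling and a low-count filter (filterByExpr, minimum count 10). All 4 groups of a fraction were fitted together. Translational efficiency was tested as the interaction of fraction and group over the 24 libraries, with each culture as a block. P-values were adjusted by Benjamini-Hochberg over all genes tested, and genes under 0.05 were called. All tests were two-sided. SE is the standard error of a log2 fold change, derived from the test statistic. CPM is the count per library scaled by edgeR after TMM. A total of 28 gene lists was tested with camera in limma 3.58.1 at a preset correlation of 0.01, with voom weights. The lists were adjusted over those of a comparison, and the calls were repeated with an estimated correlation and with fry. Lists with fewer than 3 measured members were not tested. The lists covered MAPK output, immediate early genes, cytokines, chemokines, interferon response, NF-kB feedback, TLR4 signalling and mRNA decay and ARE binding. They also covered translation initiation, ribosomal proteins, stress response and UPR, glycolysis and hypoxia, cholesterol synthesis, cell cycle, senescence and survival, DC maturation, MHC class II and LCH lesion genes. Markers of dendritic cells, macrophages and monocytes, neutrophils and granulocytes, mast cells and basophils, lymphocytes and pDC, erythroid cells, and stromal cells and osteoclasts were further lists. The mitochondrial genome, nuclear noncoding RNA and sex-linked genes completed them.

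The comparisons, the lists and the rule for named genes were chosen before the data were examined. The rule took Tnf and Braf throughout. It took for each comparison the 8 called genes with the largest rise and the 8 with the largest fall that had a mean of at least 5 CPM and no overlap between the compared groups. The overlap condition did not apply to the genotype by inhibitor comparison. Gene models without an established name were passed over. From each list the rule took up to 4 members with the smallest p. The genes printed are part of those the rule gave, picked after their values were seen, for brevity.

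The label of a pool does not state that its libraries with and without inhibitor came from the same animals. Pairing was therefore checked from the data, by the correlation over genes of the same-pool deviations from the group means in the 2 inhibitor states. A block was accepted where every pool of a genotype passed 0.1. In LCH the correlations were 0.48, 0.30 and 0.71 for pools E, F and G in total RNA and 0.24, 0.26 and 0.46 in polysome RNA. The highest correlation with the other pools' libraries was 0.35 for E and 0.297 for F in total RNA, so there E and F also deviated together and passing the rule does not show that the pairs came from the same animals. In WT pool C they were 0.097 and 0.067, so no block was accepted for WT or for the difference between the genotypes. The blocked fit for LCH still covered all libraries of a fraction. WT pools were therefore blocks in it too and entered its estimate of the spread. For the inhibitor in LCH, values with the pool as a block are given for named genes whose call it changed, for the count of calls and for the lists that camera called with it.

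Reversal was the share of genes called in LCH against WT whose inhibitor effect in LCH had the opposite sign. Both comparisons use the LCH libraries without inhibitor, so the share with no inhibitor effect was simulated 20 times. After the data were seen, the simulation was repeated with the LCH libraries of a pool correlated as measured. Both simulations drew genes independently, so their ranges leave out variation shared between genes and may be too narrow. Genes at a count of 0 in every WT polysome library of a comparison are given as lower bounds against 3 counts over the group. These bounds, and Wilson intervals at a confidence level of 95%, cover counting error only, with each count taken as an independent molecule.

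Alternatives included size factors by the median of ratios (RLE), no filter, DESeq2 1.42.0, fits of only the compared groups, limma on the rlog values and each library left out in turn. For translational efficiency they included no block and an analysis of partial variance on the rlog values. Further alternatives were chosen after seeing the data. These left out pools A and G, WT pools A and C, or genes with a count of 0 in any polysome library. Another left out the genes Rn18s, Lars2, mt-Rnr1 and mt-Rnr2 (called rRNA-type genes here, although Lars2 encodes a protein). A last one fitted only the LCH libraries with the block.

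The tests were checked on simulated data drawn with these libraries' sizes and dispersions, equal group means and known folds added to some genes. For the fit with the block, each pool had its own mean, shared by its inhibitor states, so pairing was built in. In total RNA, edgeR recovered 67% of 2-fold and 98% of 4-fold changes between LCH and WT. Of its calls there 7.82% were unchanged genes, against 25% of the DESeq2 calls. For the inhibitor in LCH edgeR recovered 73% and 96%, and 98% and 100% with the block. The values with the block hold only if the libraries of a pool are pairs, which was not shown. With the block 12.8% of the edgeR calls were unchanged genes, against 3.98% without it. For the genotype by inhibitor comparison it recovered 44% and 88%. In polysome RNA it recovered 0% of 2-, 4- and 16-fold changes between LCH and WT and 8% of 64-fold changes. For translational efficiency it recovered 0% of 2- and 4-fold, 14% of 16-fold and 64% of 64-fold changes.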

Results

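Total RNA and polysome RNA were measured in LPS-stimulated mouse BMDC from WT and LCH mice, with and without a BRAF-V600E inhibitor, with 3 libraries in each of 8 groups. The series asks how BRAF-V600E changes transcripts and their loading on polysomes after LPS, with the cytokine TNF as its subject. Total RNA libraries held 19046600 to 39792200 counts.

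The polysome libraries of the genotypes differed in depth and makeup. LCH polysome libraries held 9188920 to 30455100 counts, of which 18.0 to 65.1% fell on 4 rRNA-type genes (Rn18s, Lars2, mt-Rnr1 and mt-Rnr2). WT polysome libraries held 2017100 to 4090600 counts, of which 71.4 to 99.2% fell on these genes. Lars2, a protein-coding gene placed in this group here, took 9.80 to 29.6% of WT and 2.58 to 7.76% of LCH polysome counts. Outside them, WT polysome libraries kept 24065 to 1171450 counts and LCH polysome libraries 3206640 to 18002000. A count was seen for 1470 to 6588 genes in WT and 11077 to 36772 in LCH polysome libraries. The Spearman correlation over 9819 genes with total RNA of the same culture was 0.757 to 0.855 in LCH and 0.318 to 0.56 in WT; genes are not independent replicates. Every genotype difference in polysome RNA below was therefore also a difference between libraries of unlike depth and makeup.

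**Figure D1:**
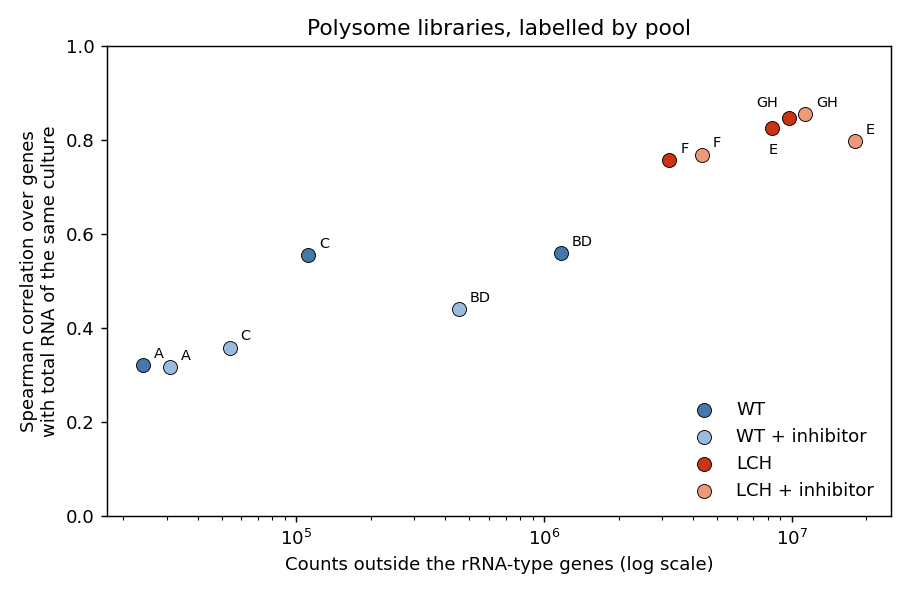
Each point is a polysome library, labelled by its pool; the x axis gives counts outside the 4 rRNA-type genes on a log scale and the y axis the Spearman correlation over genes with total RNA of the same culture. The 6 WT libraries lie at or below 0.56 and the 6 LCH libraries at or above 0.757.

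In total RNA without inhibitor, genes of MAPK output were higher and granulocyte genes lower in LCH than in WT cells, among other changes, while Tnf mRNA did not pass the test. Tnf stood at 3551 ± 532 CPM in LCH and 3044 ± 576 CPM in WT (SD, n = 3), a log2 fold change of 0.22 (SE 0.19, adjusted p = 0.39). Braf, the gene that carries the change, had a log2 fold change of -0.31 (SE 0.14, adjusted p = 0.12). Of 20 measured MAPK output genes, 13 rose, 1 fell and 6 did not pass; adjusted over the list alone, 16 rose and 1 fell. The cell cycle regulator Ccnd1 rose from 12.6 ± 3.10 to 148 ± 11.2 CPM (SD, n = 3), a log2 fold change of 3.56 (SE 0.22, adjusted p = 4.5e-06). Egr1, an immediate early transcription factor, rose by 3.43 (SE 0.27), the ERK phosphatase gene Dusp6 by 2.92 (SE 0.24) and Phlda1 by 2.18 (SE 0.19) on the log2 scale. The list was higher than other genes by camera (adjusted p = 5.5e-08), and adjusted p = 0.0054 with an estimated correlation.

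The largest rises took in the chromatin protein gene Hmga2 (log2 fold change 7.55, SE 0.44), the cytokine gene Il22 (7.11, SE 0.39), the basement membrane collagen Col4a1 (6.16, SE 0.38), the cadherin Cdh17 (6.04, SE 0.43), the integrin Itgad (5.53, SE 0.47), Cpm (5.50, SE 0.59) and the oxidase Nox1 (5.16, SE 0.50). The largest falls took in eosinophil granule genes, namely Ear1 (-5.39, SE 0.81), Epx (-4.93, SE 0.93), Prg2 (-4.76, SE 0.61), Ear6 (-4.75, SE 0.55) and Prg3 (-4.52, SE 0.66), with the basophil protease Mcpt8 (-4.35, SE 0.64), Asprv1 (-3.87, SE 0.54) and Adam11 (-3.87, SE 0.28). These 15 genes had adjusted p from 3.7e-06 to 0.0042.

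Cytokine genes moved both ways, with 5 higher, 4 lower and 13 of 22 not passing, the same numbers adjusted over the list alone. The growth factors Csf2 (log2 fold change 4.08, SE 0.33) and Csf3 (3.12, SE 0.28) and the IL-6 family member Lif (2.23, SE 0.21) rose, and Tnfsf15 fell by 1.24 (SE 0.18). Of 16 immediate early genes 6 rose, among them Btg2 (1.74, SE 0.27), Ier2 (1.71, SE 0.21) and Egr3 (1.71, SE 0.21), and 1 fell. Of 19 chemokines 4 rose, such as Cxcl9 (1.99, SE 0.42), and 3 fell, such as Ccl5 (-1.04, SE 0.17) and Ccl22 (-1.18, SE 0.30); the call of Ccl22 was lost without LCH pool E (-1.14) or F (-1.10). Camera called none of these lists (adjusted p = 0.38, 0.14 and 0.34).

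Cell cycle genes were higher in LCH, with 17 of 26 rising and none falling; adjusted over the list alone, 19 rose and 1 fell. Aurkb (log2 fold change 1.20, SE 0.24), Top2a (1.12, SE 0.26) and Cdk1 (1.04, SE 0.19) are examples; Top2a kept its size (1.10) but lost its call without the low-count filter. Of 19 cholesterol synthesis genes 12 fell, 16 adjusted over the list alone, among them Mvd (-1.47, SE 0.25) and Fdft1 (-1.16, SE 0.18). Of 17 glycolysis and hypoxia genes 6 rose and 1 fell (10 and 2 adjusted over the list alone), among them Vegfa (1.17, SE 0.23) and the glucose transporter Slc2a1 (0.88, SE 0.12). Of 15 DC maturation genes 5 fell (6 adjusted over the list alone), among them the actin bundler Fscn1 (-1.79, SE 0.36) and the homing receptor Ccr7 (-1.45, SE 0.31). Camera called these 4 lists, cell cycle with adjusted p = 1.0e-05, cholesterol synthesis with 3.4e-07, glycolysis and hypoxia with 0.034 and DC maturation with 0.0497. None held with an estimated correlation, cell cycle with adjusted p = 0.47, cholesterol synthesis with 0.47 and the other lists with 0.61.

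Lists of RNA regulation split. Of 24 genes of mRNA decay and ARE binding, 5 rose, such as Zfp36, whose protein binds AU-rich elements (log2 fold change 0.78, SE 0.11), and 2 fell, such as Zc3h12c (-0.69, SE 0.14). Of 22 translation initiation genes 5 rose and 2 fell, the repressor Pdcd4 by 1.26 (SE 0.16). Of 18 stress response genes 7 rose, such as Xbp1 (0.63, SE 0.08), and 4 fell, such as Ppp1r15a (-1.20, SE 0.08); of 78 ribosomal protein genes 3 fell. Of 17 NF-kB feedback genes 2 rose, such as Tnip3 (0.73, SE 0.14), and 4 fell, such as Tnfaip3 (-0.58, SE 0.11) and Nfkbie (-0.54, SE 0.09), and the list had a median of 0.01 and a mean of -0.07. Of 18 TLR4 signalling genes 1 rose and 5 fell, and of 29 interferon response genes 6 rose, such as Oas2 (1.78, SE 0.37) and Ifit3 (1.22, SE 0.30), and 2 fell, such as Irf1 (-0.95, SE 0.23). Of 15 senescence and survival genes 4 rose, such as Cdkn2a (2.37, SE 0.27) and Bcl2 (1.37, SE 0.22), and 2 fell. Of 9 MHC class II genes 1 rose. Camera called none of these lists (adjusted p = 0.079 to 0.59).

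Of 14 LCH lesion genes 5 rose, among them Mmp9 (log2 fold change 3.84, SE 0.42), Jag2 (2.70, SE 0.40) and Cdh1 (1.77, SE 0.24), and 2 fell (camera adjusted p = 0.21). Of 15 dendritic cell markers 5 rose, among them Dpp4 (2.71, SE 0.39), Cd209a (2.61, SE 0.26) and Kmo (2.35, SE 0.22), and 2 fell (adjusted p = 0.21). Markers of other cells moved with the genotype: 11 of 15 neutrophil and granulocyte markers fell, among them Camp (-3.26, SE 0.40), S100a9 (-2.78, SE 0.38), S100a8 (-2.49, SE 0.35) and Ltf (-2.46, SE 0.33). Camera called that list (adjusted p = 2.8e-06), but not with an estimated correlation (adjusted p = 0.47 with an estimated correlation). Of 9 mast cell and basophil markers 5 fell, such as Ms4a2 (-4.17, SE 0.44) and Prss34 (-3.73, SE 0.66), and the receptor gene Kit rose by 1.47 (SE 0.17; camera adjusted p = 0.14). Of 17 macrophage and monocyte markers 4 fell, such as Mertk (-2.09, SE 0.44) and Ly6c2 (-1.16, SE 0.23), and 2 rose (adjusted p = 0.092). Lymphocyte and pDC markers gave 1 higher and 1 lower of 10, stromal and osteoclast markers 2 and 2 of 8 (adjusted p = 0.27 and 0.81), and the 2 measured erythroid markers and 2 measured sex-linked genes did not pass. That is no sign of balanced sex, since only WT pool A held many counts of Y-linked Ddx3y and few or none of Xist. Of 8 nuclear noncoding RNAs 3 rose (adjusted p = 0.051). All 13 mitochondrial genome mRNAs fell, such as mt-Nd5 (-1.79, SE 0.27) and mt-Nd4 (-1.68, SE 0.26), with adjusted p = 3.4e-09 by camera and adjusted p = 0.47 with an estimated correlation. Mitochondrial mRNAs took 6.22 to 11.6% of WT and 1.75 to 3.74% of LCH total RNA counts.

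Across 13375 genes, edgeR called 3975, with 1983 higher and 1992 lower in LCH. Leaving out 1 library gave 2371 to 3768, and the lowest counts were those without LCH pool E (2513), WT pool BD (2593) and WT pool C (2371).

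The inhibitor comparison within LCH asks which of these transcripts move when the mutant kinase is blocked. Genes of MAPK output were lower with inhibitor, as were single cytokine genes such as Csf3 and Csf2. Of 20 MAPK output genes 6 fell and none rose, and 10 fell adjusted over the list alone. Dusp6 fell from 55.1 ± 14.4 to 10.1 ± 0.782 CPM (SD, n = 3), by 2.45 on the log2 scale (SE 0.23, adjusted p = 0.0012), and Ccnd1 fell from 148 ± 11.2 to 39.3 ± 1.53 CPM, by 1.92 (SE 0.20, adjusted p = 0.0017). Egr1 fell by 1.75 (SE 0.25), Myc by 1.72 (SE 0.25) and Phlda1 by 1.56 (SE 0.18). Camera gave adjusted p = 4.4e-16 for the list, and adjusted p = 0.00038 with an estimated correlation.

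Of 22 cytokines 5 fell and none rose, 9 adjusted over the list alone. Csf3 fell by 3.07 (SE 0.27), Csf2 by 2.54 (SE 0.30), Lif by 2.42 (SE 0.21) and Osm by 1.70 (SE 0.23). Camera called the list (adjusted p = 1.8e-07), and adjusted p = 0.13 with an estimated correlation. Immediate early genes were called too (adjusted p = 0.013, and adjusted p = 0.13 with an estimated correlation), with Egr3 falling by 1.43 (SE 0.21) and Ier2 by 1.02 (SE 0.20). Other falls were the GTPase Gimap6 (-2.39, SE 0.40), the hormone gene Fgf23 (-2.02, SE 0.32), Cdh1 (-1.72, SE 0.24), Slc2a1 (-0.67, SE 0.12), Gata2 (-0.79, SE 0.15) and Hdc (-0.74, SE 0.13). The genes that rose moved less, led by Tspan33 (1.12, SE 0.21), Dnah2 (0.83, SE 0.13), Slc25a51 (0.79, SE 0.12), Tbc1d4 (0.73, SE 0.15), the transcription factor Prdm1 (0.72, SE 0.10) and the semaphorin Sema7a (0.65, SE 0.12).

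Tnf had a log2 fold change of -0.57 with inhibitor (SE 0.19, adjusted p = 0.26), from 3551 ± 532 to 2398 ± 229 CPM (SD, n = 3), and Braf 0.08 (SE 0.14, adjusted p = 0.93). With the pool as a block, Tnf fell by 0.56 (SE 0.058, adjusted p = 1.4e-06), a block accepted from correlations that for pool F were 0.30 within the pool and 0.297 with another. The Tnf call was also made by DESeq2 (-0.57) and without the low-count filter (-0.55). In simulated data for LCH against WT, 25% of the DESeq2 calls were unchanged genes. DC maturation genes showed no call without the block but 3 higher adjusted over the list alone, and camera gave adjusted p = 0.0044 and adjusted p = 0.78 with an estimated correlation. Ccr7 (1.12, SE 0.31, adjusted p = 0.18), Socs2 (0.92, SE 0.23, adjusted p = 0.12) and Cd40 (0.52, SE 0.16, adjusted p = 0.22) did not pass. With the block, 10 of 15 rose and 2 fell, among them Ccr7 (1.13, SE 0.06), Socs2 (0.92, SE 0.07) and Cd40 (0.52, SE 0.055), and the chemokine Cxcl2 went from -0.70 (SE 0.17, adjusted p = 0.11) to -0.70 (SE 0.07, adjusted p = 6.5e-06). With the block 14 MAPK output genes fell and none rose (camera adjusted p = 9.0e-12, and adjusted p = 0.035 with an estimated correlation), and 13 cytokines fell and 2 rose (2.0e-07, and adjusted p = 0.38 with an estimated correlation). Markers of other cells also moved with the block: 5 of 15 neutrophil and granulocyte markers fell and none rose (camera adjusted p = 0.0049, against 0.16 without the block), and 6 macrophage and monocyte markers rose and 3 fell (0.097). Camera newly called chemokines lower (9 fell and 3 rose, adjusted p = 9.8e-04) and senescence and survival genes higher (8 rose and 2 fell, adjusted p = 0.0097). With an estimated correlation, adjusted p = 0.38 for neutrophil markers, 0.51 for chemokines and 0.38 for senescence and survival. DC maturation had adjusted p = 1.4e-06 with the block, and immediate early genes 0.0062 with 7 lower and 2 higher; each had adjusted p = 0.38 with an estimated correlation.

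Camera also called lists with small shifts and no held call with an estimated correlation. These were ribosomal proteins (median log2 fold change 0.10, adjusted p = 2.2e-04; adjusted p = 0.84 with an estimated correlation), glycolysis and hypoxia (-0.05, 0.013; adjusted p = 0.78), dendritic cell markers (-0.14, 0.013; adjusted p = 0.45) and the mitochondrial genome (-0.33, 0.013; adjusted p = 0.80). With the block these lists had 2 higher, 7 lower and 1 higher, 5 lower and 1 higher, and 3 lower, and were again called (adjusted p = 1.7e-05, 0.0039, 0.0062 and 8.7e-05). With an estimated correlation, adjusted p = 0.77, 0.45, 0.48 and 0.48 with the block. Over all genes edgeR called 99, with 19 higher and 80 lower, and 1384 had an unadjusted p under 0.05. With the block it called 2302, with 1070 higher and 1232 lower. In data simulated with pairing built in, 12.8% of such calls were unchanged genes, against 3.98% in data without pairing and without the block. DESeq2 without a block called 328. Without the untreated library of pool F the calls of Gimap6 (-2.53), Fgf23 (-2.17), Egr1 (-1.63), Myc (-1.75), Osm (-1.59), Cdh1 (-1.61), Egr3 (-1.49), Ier2 (-0.93), Slc2a1 (-0.59), Gata2 (-0.85), Hdc (-0.83), Tspan33 (1.19), Dnah2 (0.85), Slc25a51 (0.76), Tbc1d4 (0.66) and Sema7a (0.66) were lost, 16 in all. Without the untreated libraries of E and G, 13 and 8 named genes lost their calls, Prdm1 among the former (0.68), and without the inhibitor libraries of E, F and G 8, 14 and 6 did, with no change of sign. Csf3, Csf2, Dusp6, Lif, Ccnd1 and Phlda1 kept their calls without any 1 of the 6 libraries. The unblocked count fell to 62 without the inhibitor library of pool E, 31 without that of F, 59 without that of G, and to 35 and 20 without the untreated libraries of E and F.

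**Figure D2:**
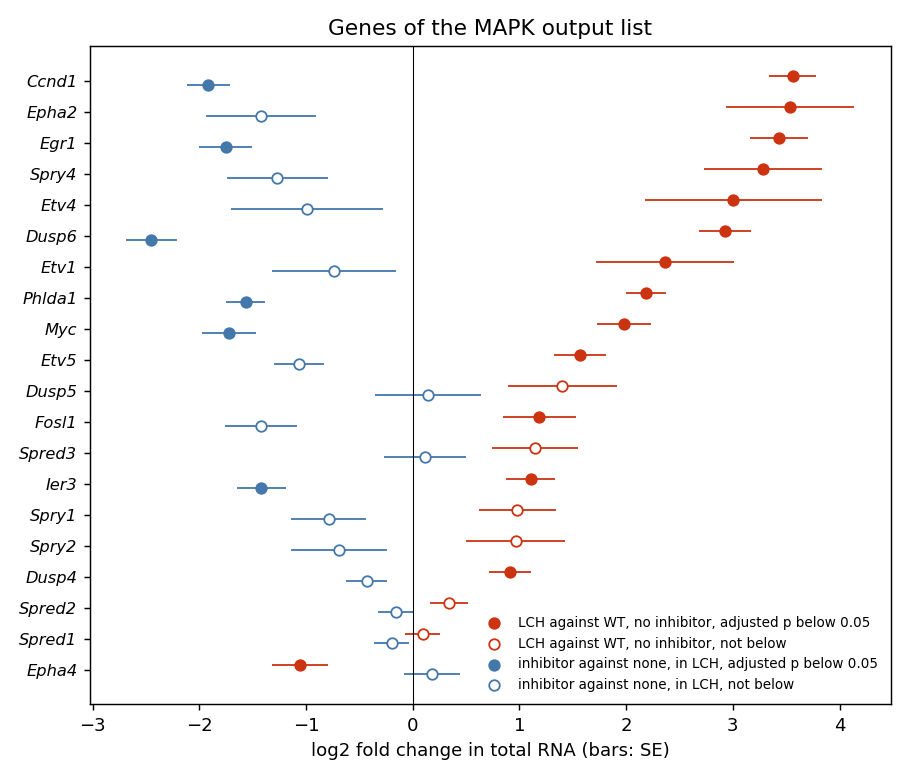
Points are log2 fold changes in total RNA of the MAPK output genes for LCH against WT without inhibitor and for the inhibitor in LCH, with bars of 1 SE (n = 3 libraries a group); filled points have an adjusted p under 0.05. Of 20 genes, 13 rose and 1 fell in LCH, and 6 fell with inhibitor.

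**Figure D3:**
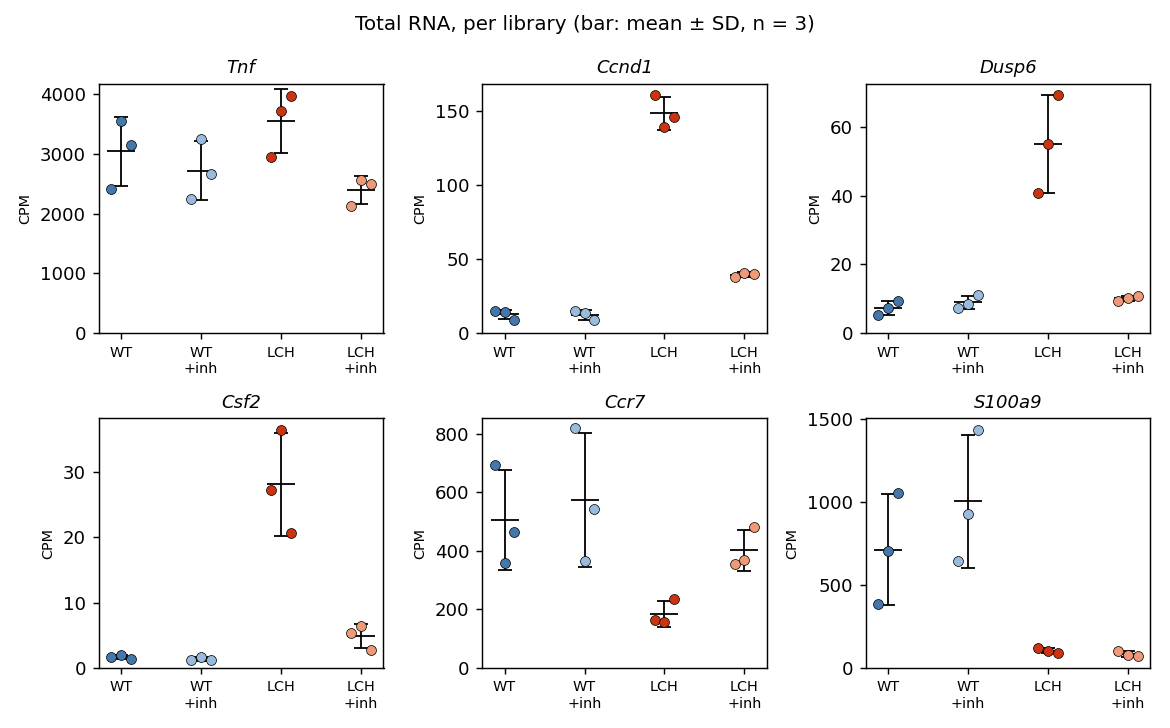
Points are CPM in total RNA of single libraries for 6 genes in the 4 groups, with bars for the mean and SD (n = 3); each axis starts at 0. Ccnd1 stood at 148 CPM in LCH, 39.3 in LCH with inhibitor and 12.6 in WT.

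Of the 3975 genes called in total RNA, 2838 moved in the opposite direction with inhibitor in LCH, a share of 71.4%. Simulations without an inhibitor effect gave 59.9 to 62.7% with independent libraries and 56.6 to 58.9% with the LCH libraries of a pool correlated as measured. Genes were drawn independently in both, so the ranges leave out variation shared between genes and may be too narrow. The covariance of the fold changes was -0.106, against -0.150 to -0.0964 in the former simulations and -0.0862 to -0.0487 in the latter. Among genes called in both comparisons, 65 were higher in LCH and fell with inhibitor, where independent calls would give 11.9. A further 15 were lower in LCH and rose, where they would give 2.83. Opposite to that, 0 were higher and rose and 2 were lower and fell. The simulations without an inhibitor effect gave 0 and 0 to 1 for the 65 and the 15. That is by construction, since hardly any gene is then called for the inhibitor, and says nothing about direction. Both comparisons share the untreated LCH libraries, which raises such overlaps, and 3 libraries a group are too few to split.

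In WT, the inhibitor comparison asks what the compound does without its mutant target. None of 20 MAPK output genes was called, with a median log2 fold change of 0.06, and none of 22 cytokines; Tnf had -0.16 (SE 0.19, adjusted p = 0.77) and Braf 0.11 (SE 0.14, adjusted p = 0.80). Of 8 nuclear noncoding RNAs 2 rose, 4 adjusted over the list alone, with Neat1 higher by 1.67 (SE 0.27) and Zfas1 by 0.61 (SE 0.10). Camera gave that list adjusted p = 2.6e-05, and adjusted p = 0.10 with an estimated correlation. Other genes that rose were Dpep3 (1.99, SE 0.23), Sap25 (1.91, SE 0.28), Pde1b (1.73, SE 0.31), Fam193b (1.42, SE 0.13), Brf1 (1.33, SE 0.09) and Mfsd7a (1.24, SE 0.16), and Ephx1 (-0.77, SE 0.14) and Sulf2 (-0.56, SE 0.10) fell. The lysozyme gene Lyz2 (-0.76, SE 0.24, adjusted p = 0.20) and the transcription factor gene Batf3 (0.97, SE 0.20, adjusted p = 0.055) did not pass. Camera also called cholesterol synthesis lower (median -0.21, adjusted p = 3.2e-05), ribosomal proteins lower (-0.07, 0.0012), macrophage and monocyte markers lower (-0.47, 0.0045), chemokines lower (-0.23, 0.017), and neutrophil (0.38, 0.017) and mast cell markers (0.39, 0.017) higher. For each of these, adjusted p = 0.95 with an estimated correlation. Without the untreated library of pool C the calls of Dpep3 (1.97), Sap25 (1.68), Pde1b (1.64), Neat1 (1.49), Mfsd7a (1.20), Zfas1 (0.58), Ephx1 (-0.74) and Sulf2 (-0.58) were lost. Without the untreated libraries of A and BD 1 and 7 of these genes lost their calls, and without the inhibitor libraries of A, BD and C 3, 6 and 7 did, while Fam193b and Brf1 kept theirs without any 1 of the 6 libraries. The balance of calls depended on the setting, with 205 higher and 116 lower by DESeq2 and 209 higher and 90 lower without a filter. As reported, edgeR called 95 over all genes, with 90 higher and 5 lower. The count was 6 when only the WT groups were fitted, 244 without the untreated library of pool A, and 37, 15, 13, 11 and 8 without the inhibitor libraries of A, BD and C and the untreated libraries of BD and C.

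The difference between the inhibitor effects of the genotypes was tested directly. The effect on MAPK output was lower in LCH than in WT, with 4 of 20 genes lower and none higher, and 7 lower adjusted over the list alone (camera adjusted p = 3.7e-07, and adjusted p = 0.0079 with an estimated correlation). Dusp6 differed by -2.75 (SE 0.33), Myc by -2.10 (SE 0.35), Ccnd1 by -1.89 (SE 0.29) and Phlda1 by -1.41 (SE 0.26) on the log2 scale. Among cytokines Csf3 (-3.04, SE 0.38) and Lif (-2.53, SE 0.28) differed, and Csf2 did not pass (-2.24, SE 0.45, adjusted p = 0.069). Tnf did not pass (-0.41, SE 0.26, adjusted p = 0.57), nor did Braf (-0.02, SE 0.20, adjusted p = 0.98). Over all genes 54 were called, with 7 higher and 47 lower, and 1626 had an unadjusted p under 0.05. Csf3 lost its call without the untreated library of WT pool BD (-2.96) or the inhibitor library of WT pool C (-2.92). Leaving out 1 of the 12 libraries cost 7 to 12 of the genes named here or in the closing part their calls. When lost, the values were -1.83 to -2.29 for Myc, -1.69 to -1.97 for Ccnd1 and -1.26 to -1.57 for Phlda1. Dusp6 and Lif kept their calls without any 1 library. Without 1 of the 12 libraries the count was 7 to 66, and it was 54 or more only without the untreated library of WT pool A.

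With inhibitor in both genotypes, LCH total RNA kept many of its differences from WT. Il22 (log2 fold change 5.68, SE 0.37), Itgad (5.15, SE 0.47), Col4a1 (5.07, SE 0.36), Cpm (4.99, SE 0.57), the NK receptor gene Klrd1 (4.02, SE 0.44), arginase Arg1 (3.93, SE 0.30) and Cdh17 (3.80, SE 0.39) rose, and Ear1 (-6.79, SE 0.86), Epx (-5.86, SE 0.96), Prg2 (-5.56, SE 0.64), Mcpt8 (-4.73, SE 0.64) and the neutrophil granule gene Olfm4 (-4.42, SE 0.51) fell. Of 20 MAPK output genes 5 rose and 1 fell, 8 and 1 adjusted over the list alone, with Ccnd1 (1.67, SE 0.21), Egr1 (1.57, SE 0.26) and Phlda1 (0.77, SE 0.18) higher. Camera called the list (adjusted p = 0.0076; adjusted p = 0.27 with an estimated correlation). Of 22 cytokines 3 rose and 4 fell, with Csf2 higher by 1.84 (SE 0.32) and the interleukin genes Il23a (-1.74, SE 0.17), Il12b (-1.32, SE 0.18) and Il12a (-1.15, SE 0.19) lower. Tnf (-0.18, SE 0.19, adjusted p = 0.53) and Braf (-0.33, SE 0.14, adjusted p = 0.12) did not pass. Zfp36 (1.16, SE 0.11), Tnip3 (1.45, SE 0.14), Cdkn2a (2.68, SE 0.27), Mmp9 (3.15, SE 0.41) and Spp1, which encodes osteopontin (2.21, SE 0.44), rose.

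The same lists of other cells moved again: 14 of 15 neutrophil markers fell, such as S100a9 (-3.57, SE 0.39) and Ltf (-3.51, SE 0.35), as did 8 of 9 mast cell and basophil markers, while Kit rose by 1.60 (SE 0.17), and 12 of 13 mitochondrial mRNAs fell. Camera called these lists (adjusted p = 3.3e-10, 4.3e-04 and 5.7e-13), and each had adjusted p = 0.36 with an estimated correlation. Cell cycle genes had 12 of 26 higher (adjusted p = 1.1e-05), cholesterol synthesis 7 of 19 lower (5.1e-04), MHC class II 4 of 9 higher (0.0028) and ribosomal proteins none of 78 called (0.0028). With an estimated correlation these had adjusted p = 0.59, 0.59, 0.59 and 0.79. Over all genes 2718 were called, with 1240 higher and 1478 lower. Without LCH pool E, LCH pool F or WT pool C the counts were 1669, 1610 and 1470, and Phlda1 lost its call without LCH pool E (0.70) or F (0.60) or WT pool A (0.71) or BD (0.70). Of the genes called with and without inhibitor, 851 were higher in both (184 if independent), 1027 lower in both (220 if independent) and 23 opposite. Both comparisons use the same pools, which raises such overlaps, and no value that allows for this was computed.

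In polysome RNA without inhibitor, cytokine, chemokine, antigen presentation and cell cycle transcripts were among those higher in LCH, and Tnf did not pass. Tnf stood at 532 ± 112 CPM in LCH and 85.9 ± 57.0 CPM in WT (SD, n = 3), a log2 fold change of 2.62 (SE 0.98, adjusted p = 0.072), on 7430 to 29018 counts in LCH and 10, 604 and 187 in WT. With WT pools A and C left out, which keeps only pool BD in WT, Tnf had 2.74. Over the 15 alternative settings it ranged from 1.20 to 3.25, with adjusted p up to 0.78. Csf2 and Csf3 had no count in the 3 WT libraries and were at least 27.8-fold and 32.9-fold higher in LCH. On the same terms Phlda1 was at least 47.6-fold, the mitotic kinase gene Cdk1 65.6-fold, Birc5 69.1-fold, Cd82 212-fold and Chmp2a 282-fold higher. Each bound treats a count as an independent molecule, which was not tested. Of 6588 genes with a count in WT pool BD, 5973 had at least 10, so the true folds may lie below the bounds. The bounds rest mostly on WT pool BD. Without it they were 5.29-fold for Csf2, 6.24-fold for Csf3, 9.05-fold for Phlda1, 12.4-fold for Cdk1, 13.1-fold for Birc5, 40.3-fold for Cd82 and 53.5-fold for Chmp2a. Over 14 other settings the adjusted p of Csf2 and Csf3 reached 0.0945 and 0.0921. The chemokine genes Ccl4 (log2 fold change 4.83, SE 1.13, adjusted p = 0.013) and Ccl3 (3.12, SE 1.00, adjusted p = 0.040), the MHC class II genes H2-Ab1 (4.05, SE 1.17), H2-Aa (3.87, SE 1.01) and H2-Eb1 (3.73, SE 1.13), Rplp2 (4.39, SE 1.10) and the pyruvate kinase gene Pkm (2.49, SE 0.83) rose. Ccl3, H2-Aa, H2-Ab1, H2-Eb1, Rplp2 and Pkm lost their calls with RLE factors, at 2.00, 2.56, 2.91, 2.62, 3.08 and 0.99. Without WT pool C, Ccl3 (3.61), H2-Ab1 (4.21) and Pkm (2.80) also lost their calls, without WT pool A H2-Ab1 (3.61) did, and Ccl3, H2-Eb1 and Pkm did without WT pool BD (3.40, 3.90 and 2.31), LCH pool E (3.35, 3.81 and 2.72) or LCH pool G (3.06, 3.68 and 2.70). The mitochondrial rRNAs mt-Rnr1 (-6.75, SE 1.40) and mt-Rnr2 (-6.63, SE 1.5) and the receptor genes Olfr1039 (-9.33, SE 1.82) and Olfr109 (-9.65, SE 1.96) fell. Braf had -0.89 (SE 0.99, adjusted p = 0.56).

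Of 26 cell cycle genes 11 rose in polysome RNA and 13 adjusted over the list alone, of 22 cytokines 6 and 6, of 9 MHC class II genes 3 and 4, of 29 interferon response genes 1 and 0, of 78 ribosomal protein genes 1 and 0, and no member of these lists fell. Camera called them (adjusted p = 0.0045, 0.035, 0.018, 0.0039 and 0.018) and called the mitochondrial genome lower (0.010) with no gene passing. None held, with adjusted p = 0.60 with an estimated correlation, or 0.79 for ribosomal proteins. The median log2 fold change over all genes was 1.62 with TMM and 0.46 with RLE. Over 9902 genes edgeR called 2191, with 2120 higher and 71 lower, and 1911 of the 2120 (90.1%) had no count in any of the 3 WT libraries. The share of calls that were higher went from 96.8% to 85.0% with RLE, where 1462 were called, to 57.4% without a filter, where 921 were called, and to 55.3% with DESeq2, where 1119 were called. On rlog values limma called 1 higher and 20 lower. None was called with pools A and G left out.

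Translational efficiency, the change in polysome RNA beyond that in total RNA, is what the series set out to define. Ccl4 (log2 fold change 5.19, SE 1.16, adjusted p = 0.016), the interferon-induced genes Isg15 (6.08, SE 1.66) and Bst2 (4.53, SE 1.40) and Rplp2 (5.19, SE 1.19) were higher in LCH. So were markers of other cells, namely Prss34 (6.73, SE 1.39), S100a8 (4.56, SE 1.24), C1qc (4.17, SE 1.17) and Apoe (4.11, SE 1.23). The mitochondrial rRNAs mt-Rnr1 (-5.39, SE 1.39) and mt-Rnr2 (-5.45, SE 1.45) were lower. Tnf did not pass (2.81, SE 1.06, adjusted p = 0.098), nor did Braf (0.28, SE 1.26, adjusted p = 0.96). Tnf was called without the culture block (2.52). With WT pools A and C left out, which keeps only pool BD in WT, it had 3.09. Over the 16 alternative settings Tnf ranged from 0.90 to 3.39, with adjusted p up to 0.74. Its reported value lay near the median of 2.88 over all genes, which also takes in genes with no count in WT polysome RNA. With RLE factors or with pools A and G left out, no gene was called for translational efficiency, nor without the LCH culture of pool E or of G. Without that of LCH pool F, Ccl4 (5.26), Isg15 (6.03), Bst2 (4.30), Rplp2 (4.84), S100a8 (4.40), C1qc (4.35) and Apoe (4.26) lost their calls. Without that of WT pool A, Bst2 (3.97), Apoe (3.65), mt-Rnr1 (-4.68) and mt-Rnr2 (-4.67) did, and without that of WT pool C, Bst2 (4.29), Apoe (3.65), C1qc (3.97), mt-Rnr1 (-4.90) and mt-Rnr2 (-5.01).

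Of 22 cytokines 5 were higher in translational efficiency (9 adjusted over the list alone), of 26 cell cycle genes 9 (12), of 15 neutrophil markers 5 (10), of 8 mast cell and basophil markers 4 (7), of 17 macrophage and monocyte markers 3 (7), and none was lower. Of the 27 lists tested, camera called 17 higher and 0 lower, and none held; the smallest was adjusted p = 0.18 with an estimated correlation. The median over all genes was 2.88 with TMM and 1.59 with RLE. Of 15212 genes edgeR called 1791, with 1740 higher and 51 lower (97.2% higher). The count was 0 with RLE, 41 by partial variance (75.6% higher) and 1087 by DESeq2 (75.8% higher), and it was 0 without the LCH culture of pool E, 0 without that of G and 641 without that of F.

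With inhibitor in LCH, no gene passed in polysome RNA or in translational efficiency by edgeR, with 38 and 55 genes at an unadjusted p under 0.05; DESeq2 called 5 and 1. In simulated data edgeR recovered 0% of 2-, 4- and 16-fold changes and 6% of 64-fold changes for this comparison in polysome RNA, so calls could hardly be made. In polysome RNA the log2 fold changes were -3.03 for Csf2 (SE 0.86), -2.78 for Csf3 (SE 0.91), -1.89 for Dusp6 (SE 0.80), -1.69 for Myc (SE 0.65), -0.51 for Tnf (SE 0.93) and 0.07 for Braf (SE 0.94), each with adjusted p = 1.00. Camera called cytokines (adjusted p = 2.4e-04), MAPK output (5.0e-04) and the mitochondrial genome (0.016) lower as lists, and adjusted p = 0.37, 0.37 and 0.85 with an estimated correlation. With the pool as a block edgeR called 0 genes, 5 MAPK output genes fell adjusted over the list alone, and camera gave that list adjusted p = 4.4e-05 and adjusted p = 0.10 with an estimated correlation. Cytokines (8.1e-07) and the mitochondrial genome (0.035) were again called lower with the block, chemokines (0.0040) and ribosomal proteins (0.0095) newly lower and DC maturation (0.042) newly higher. With an estimated correlation these had adjusted p = 0.092, 0.88, 0.43, 0.88 and 0.43. Csf2 passed with only the LCH libraries fitted with the block (-3.09), where 29 genes were called. In translational efficiency the inhibitor effects were 0.02 for Tnf (SE 1.02), -0.57 for Csf2 (SE 0.75) and -0.16 for Braf (SE 1.02), each with adjusted p = 1.00. Of the 2191 genes called in polysome RNA, 50.4% moved in the opposite direction with inhibitor, against 54.7 to 59.9% in simulations without an inhibitor effect and 52.9 to 57.3% with correlated pools. These ranges too come from genes drawn independently and may be too narrow. The simulations also called 2967 to 3297 genes, or 2984 to 3219 with correlated pools, against the 2191 observed. They thus did not reproduce these data, and the observed share cannot be read against them.

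In WT polysome RNA no gene was called with inhibitor by edgeR, with 3455 at an unadjusted p under 0.05, and DESeq2 called 1402. Tnf had a log2 fold change of -0.68 (SE 0.93, adjusted p = 0.82), on 3, 246 and 51 counts with inhibitor. Braf had no count in the WT libraries with inhibitor and 49 counts in 1 without. The edgeR count was 492, 74 and 2329 without the untreated library of pool A, BD or C. NF-kB feedback was called lower as a list (adjusted p = 1.0e-04; adjusted p = 0.97 with an estimated correlation). The genotype by inhibitor comparison in polysome RNA also gave 0 genes by edgeR, with 2849 at an unadjusted p under 0.05, and 631 by DESeq2. Tnf had 0.17 (SE 1.31, adjusted p = 1.00), and NF-kB feedback was called higher (adjusted p = 9.1e-05; adjusted p = 0.95 with an estimated correlation).

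With inhibitor in both genotypes, Tnf in polysome RNA was higher in LCH by 2.79 on the log2 scale (SE 0.99, adjusted p = 0.039), at 373 ± 14.8 CPM against 53.5 ± 39.9 CPM (SD, n = 3). The log2 fold change of Tnf lay below the median of 6.95 over all genes. That median reflects missing WT counts, since these WT libraries held a count for only 1470 to 3807 genes and 9902 were tested. It is therefore no measured rise against which Tnf can be ranked. The Tnf call was lost with RLE factors (1.53), DESeq2 (1.49), rlog values (1.40) and no filter (2.88). The same held among genes counted in every library (1.74) and with pools A and G left out (2.33). The Tnf call was also lost without the inhibitor libraries of LCH pool E (3.11), F (2.76) or G (3.10) or of WT pool A (2.35) or BD (2.95). Pkm (3.30, SE 0.86), Rpl4 (3.03, SE 1.03) and H2-Aa (2.57, SE 0.95) rose, with values also below 6.95. Tnfsf15 (-4.54, SE 0.96), the nuclear RNA Malat1 (-3.65, SE 1.22), mt-Rnr1 (-9.23, SE 1.56), mt-Rnr2 (-8.85, SE 1.65) and Olfr1039 (-9.72, SE 1.84) fell. Braf had no count in WT and was at least 2.91-fold higher in LCH, without passing (adjusted p = 0.056), and without WT pool BD the counts gave no bound. With RLE factors none of these genes passed, nor did they without WT pool BD. Rpl4 lost its call whichever of the 6 libraries was left out (2.56 to 3.58). H2-Aa was also lost without LCH pool E (3.01), LCH pool F (2.77) or WT pool A (2.18), and Malat1 without LCH pool E (-2.99), LCH pool G (-3.00) or WT pool A (-2.42).

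Of 29 interferon response genes 12 rose in this comparison, of 17 NF-kB feedback genes 8, of 26 cell cycle genes 20, of 14 DC maturation genes 8, of 17 glycolysis and hypoxia genes 6 and of 9 MHC class II genes 5, and none fell. Adjusted over the list alone these were 12, 8, 21, 8, 6 and 5. Camera called each of them higher (adjusted p = 5.6e-06, 2.5e-06, 0.0039, 5.2e-04, 0.0022 and 0.0081) and nuclear noncoding RNA (0.0018) and the mitochondrial genome (0.0019) lower. None held, with adjusted p = 0.16 to 0.68 with an estimated correlation. Of 9902 genes 4025 were called, with 3916 higher and 109 lower, and 3528 of the 3916 (90.1%) had no count in any WT library. The median over all genes was 6.95 with TMM and 6.90 with RLE. The count was 0 with RLE, 0 without the WT inhibitor library of pool BD, and 681 by DESeq2 (74.3% higher). Without a filter 60.8% of 762 calls were higher. With limma on rlog values the balance was the opposite, with 14 higher and 28 lower.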

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

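In this part, the tests of the scaling factor, of the rRNA-type genes and of an equal drop of every other cell type were chosen only after the result was seen.

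The inhibitor effect differed between LCH and WT in total RNA by the test of the difference itself for 54 genes. Among those named, it was lower in LCH for Dpep3 (-3.04), Csf3 (-3.04), Dusp6 (-2.75), Lif (-2.53), Myc (-2.10), Cdh1 (-2.06), Ccnd1 (-1.89), Egr3 (-1.75), Phlda1 (-1.41) and Hdc (-1.10) on the log2 scale. It was higher for Slc49a4 (1.00), Prdm1 (0.88), Arl5a (0.70), Adora2a (0.63) and C9orf72 (0.57). As lists, the effects on MAPK output (adjusted p = 3.67e-07), immediate early genes (0.0352), cytokines (0.0134), neutrophil markers (0.0134), mast cell markers (0.0263), the mitochondrial genome (0.0161) and nuclear noncoding RNA (1.64e-05) were lower in LCH. Those on ribosomal proteins (3.08e-07), cholesterol synthesis (0.00393) and macrophage markers (0.0170) were higher. Of these lists, only MAPK output held with an estimated correlation (adjusted p = 0.00787), and the others had adjusted p = 0.11 to 0.76.

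Other splits of the same libraries were fitted to see how often they give as many genes. For the interaction in total RNA, 5 of 100 splits gave 54 or more, with a highest other count of 918, so chance was not excluded for the count. In polysome RNA the real count was 0, so 100 of 100 splits gave as many by construction, which says nothing about chance. Comparisons of 3 against 3 libraries allow 10 splits, too few for a share under 0.05. For LCH against WT only 1 of the 10, the real one, reached the real count in total RNA (3975, highest other 1), polysome RNA (2191, highest other 12) and translational efficiency (1791, highest other 2). The same held with inhibitor in total RNA (2718, highest other 0) and polysome RNA (4025, highest other 10), and for the inhibitor in LCH in total RNA (99, highest other 1). With the pool as a block, the inhibitor in LCH gave 2302, and the other splits that part every pool gave 0 to 2; the 4 such splits are too few for a share under 0.05. In polysome RNA and translational efficiency the inhibitor in LCH gave 0, which 10 of 10 splits reach by construction, and the highest other was 0. For the inhibitor in WT, 2 of 10 splits reached the real 95 in total RNA, and the other gave 721. It set pool A with and without inhibitor and the treated library of C against the rest, so it parted pool C. Why it gave more genes was not tested. In WT polysome RNA the real count was 0, which 10 of 10 splits reach by construction. The highest other count was 1480, for pools A and BD without inhibitor and A with it against the rest. Other splits that kept the libraries of pool A together gave 4, 0 and 228, and the cause was not tested.

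Of the genes called in polysome RNA without inhibitor, 96.8% were higher in LCH. TMM scaling and the rRNA-type genes in the library size cannot be told apart from other sources of the excess, since 90.1% of the higher calls had no count in any WT library and no scaling turns their direction; 85.0% were higher by median-of-ratios factors in edgeR and 96.9% with the rRNA-type genes left out. DESeq2 gave 55.3%, edgeR without a filter 57.4% and limma on rlog values 1 of 21 calls higher. Read depth alone does not account for the low resemblance of WT polysome libraries to their total RNA. In 6 of 6 cases the WT library was less like it than every LCH library thinned to the same depth. Thinning draws single reads, so it cannot speak to the sampling of few RNA molecules. In WT pool BD without inhibitor, 5973 of 6588 genes with a count had at least 10. Unequal depth, and poor recovery from the WT gradients, cannot be told apart from a difference in polysome loading, because thinning the LCH libraries to WT depth left 6 calls, of which 0% were higher, and 53.0% of the genes with an unadjusted p under 0.05 were higher; with inhibitor the thinned libraries gave 266 calls, of which 226 were higher.

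The pool G and GH libraries of LCH held counts for many more genes than the other LCH libraries, and satellite-type gene models took 24.7% of total RNA counts with inhibitor (95% Wilson interval 24.73 to 24.76) and 1.82% without. Genomic DNA may be a source, since in 4 of 4 of these libraries olfactory and vomeronasal receptor genes took a larger share of counts than in every other LCH library of the fraction, at 0.0517 to 0.131% against at most 0.00398%, and spread over 1142 to 1346 of 1450 receptor genes against 11 to 55. The share alone is no sign of DNA, since WT polysome libraries held 0.0746 to 2.43% on 10 to 18 receptor genes. A single DNA source for both is argued against, since the ratio of satellite-type to receptor counts differed 13.1-fold between the inhibitor states in total RNA and 22.8-fold in polysome RNA. No biological explanation was tested.

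Granulocyte markers, and 5 of 9 mast cell or basophil markers, were lower in LCH total RNA, with list medians of -2.46 and -2.22, but Kit rose by 1.47, camera did not call the mast cell list (adjusted p = 0.14), and the granulocyte list lost its call with an estimated correlation (adjusted p = 0.47). Fewer such cells in the LCH cultures is a candidate explanation, since within groups the markers rose and fell together across the 12 libraries more than at least 99.8% of 1000 random lists of like level (mean r 0.592 and 0.301). An equal drop of every other cell type could not be decided, since macrophage and monocyte markers need not come from cells apart from the cultured dendritic cells. In 1 of 3 pairs of marker lists the interquartile ranges did not overlap, neutrophil (-2.71 to -1.12) against macrophage and monocyte markers (-0.81 to -0.15, median -0.50). The range of the mast cell and basophil list (-3.73 to 0.03) overlapped that of the neutrophil list. A genotype effect on these genes within cells, or on the differentiation of the cultures, stays open and untested. Among the abundant markers, S100a9 stood at 382 to 1052 CPM in untreated WT libraries and 90.6 to 117 in LCH, and Prss34 at 33.3 to 112 and 4.25 to 8.37.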

How the results depend on the processing

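The settings that left out pools A and G, WT pools A and C or the rRNA-type genes, kept genes with a count in each polysome library, or fitted the LCH libraries alone with the pool as a block were chosen only after the data were seen. Where a group kept 1 pool, the lone library was assumed to vary like those of the other groups. What caused the shifts below was not tested.

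Of 2988 values under other settings, for 219 gene results that the naming rule gave and most of which the text prints, 2403 (80.4%) kept their direction and side of the threshold, 498 lost their call, 50 gained one and 37 changed sign. In total RNA 99.4% of those for LCH against WT kept both, against 54.6% for the interaction and 52.8% for translational efficiency in LCH against WT. Of 101 alternative counts 50 lay within 1.5 times the reported one, as did 49 of 84 counts without 1 library or culture.

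For LCH against WT in total RNA the 6 alternatives gave 2786 to 5006 genes, and 1868 to 3881 with inhibitor. Without 1 library the ranges were 2371 to 3768 and 1470 to 2368.

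Without a filter the counts were 921 for LCH against WT in polysome RNA and 762 with inhibitor, 342, 7 and 3 for the inhibitor in LCH (total RNA, polysome RNA, translational efficiency), 299 and 145 for the inhibitor in WT (total, polysome), and 269 and 19 for the interaction. DESeq2 gave 1119, 681, 328, 5, 1, 321, 1402, 203 and 631 in the same order, and 1087 for translational efficiency in LCH against WT. RLE size factors gave 0 for the latter and 0 for LCH against WT with inhibitor in polysome RNA. On the deposited rlog values limma gave 21 for LCH against WT and 42 with inhibitor in polysome RNA, 57 and 1 for the inhibitor in LCH (total, polysome) and 4 for the inhibitor in WT polysome RNA, and partial variance gave 41 for translational efficiency. Without the block translational efficiency gave 3845. With only the groups compared, the inhibitor in WT total RNA gave 6.

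Leaving out WT pools A and C gave 5284 and 6567 for LCH against WT in polysome RNA without and with inhibitor, 5254 for translational efficiency, 3 and 5 for the inhibitor in LCH (polysome RNA, translational efficiency), 3706 for the inhibitor in WT polysome RNA and 3463 for the interaction there. Leaving out pools A and G gave 0 for LCH against WT in polysome RNA without and with inhibitor and for translational efficiency, 400 for the inhibitor in WT total RNA and 179 for the interaction in total RNA. Genes with a count in each polysome library gave 31, 46 and 23, a setting that leaves out genes with no count in WT by construction and so says nothing about the balance of higher and lower calls.

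Without 1 library, translational efficiency gave 0 (LCH E or G) to 2198, the inhibitor in LCH total RNA 20 (untreated F) to 73, the inhibitor in WT 8 (untreated C) to 244 (untreated A) in total and 0 to 2329 (untreated C) in polysome RNA, the interaction in total RNA 7 (untreated WT BD) to 66, and LCH against WT with inhibitor in polysome RNA 0 (WT BD) to 3425.

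The pool as a block gave 2302 for the inhibitor in LCH total RNA, in a fit where WT pools were blocks too. The LCH libraries alone with the block gave 2579, and 29 in polysome RNA. In total RNA Tnf, Ccr7, Socs2, Cd40 and Cxcl2 gained calls with the block and no other gene named for that comparison changed its call, while with the LCH libraries alone Lif (-2.43) lost its call. The labels do not state that libraries of 1 pool letter are pairs. Deviations from the group means correlated within each LCH pool (r 0.30 to 0.71 in total RNA, 0.24 to 0.46 in polysome RNA), but for WT pool C only at 0.0971 and 0.067. Values with the block for the inhibitor in WT (2899 total, 2666 polysome) and the interaction (2639 and 2395) therefore stand here only. No paired analysis was possible for LCH against WT because the genotypes share no pool, so the block could not be fitted there.

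Of 76 list calls 3 held with an estimated correlation. With fry the number was 90, with the block 92, and without 1 library or culture 73 to 91. The share of LCH differences in total RNA with the opposite sign under the inhibitor was 73.3% for genes with a fold of at least 1.5, where simulations without an inhibitor effect gave 59.5 to 63.2% with independent libraries and 56.5 to 59.3% with correlated pools, and it was 71.3% with the block. Genes were drawn independently in these simulations, so the ranges may be too narrow.

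Signs changed mostly for Braf and Tnf at values that were not called. For Tnf these were LCH against WT in total RNA without pools A and G (-0.0079), the inhibitor in LCH translational efficiency without a filter (-0.10), with only the groups compared (-0.081), without WT pools A and C (-0.17) and without 1 culture (-0.069 to 0.0895), and the interaction in polysome RNA without WT pools A and C (-0.091) and without 1 library (-0.42 to 0.69). For Braf on rlog values they were the inhibitor in LCH (-0.027) and WT (-0.027) and the interaction (6e-04) in total RNA, with ranges without 1 library of -0.054 to 0.20 for LCH and -0.16 to 0.10 for the interaction. Braf in translational efficiency, LCH against WT, gave -1.16 with RLE, -0.67 without the block, -0.91 by partial variance, -1.15 without WT pools A and C, -0.27 without pools A and G, -1.21 with DESeq2 and -0.79 to 10.53 without 1 culture; in polysome RNA it gave -1.40 to 8.30, the latter without WT pool BD, where WT was at 0. Braf with the inhibitor in LCH polysome RNA gave -0.0066 with the block, -0.0156 in LCH alone with the block and -0.32 to 0.32 without 1 library. Its translational efficiency gave 0.48 by partial variance and -0.39 to 0.14 without 1 culture. With the inhibitor in WT polysome RNA it gave -9.73 to 0, the latter without untreated WT pool BD. Prss34 in translational efficiency gave -0.48 by partial variance.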

Other observations

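This part gives counts and no tests. The pools also differed in sex-linked transcripts. WT pool A held 1204 and 1266 counts of the Y-linked Ddx3y in total RNA without and with inhibitor, and 0 and 34 counts of Xist. WT pools BD and C held 0 counts of Ddx3y and 4157 to 10408 of Xist in total RNA, and the LCH pools 0 to 4 of Ddx3y and 7224 to 19017 of Xist. Sex-linked makeup was thus not balanced between the genotypes, and no comparison adjusted for it.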
